A study of Mus musculus with 39 samples.

How the data were processed

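The measurements are single-cell transcriptomes by CEL-Seq2 of mouse bone marrow progenitors, of cells cultured from them and of embryonic stem cells, in 39 libraries of 16 groups. The groups follow the titles, surface markers and gates stated per library. For the embryonic stem cell libraries the tissue entry reads bone marrow, while the study's design text and the titles speak of embryonic stem cells, and they were treated as embryonic stem cells. The contents of culture gates 16, 17 and 18 are not stated. Cells of the 11 mixed-gate libraries carry no gate, so these 11 were described and not compared.

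Per the submitters' processing notes, reads were processed with bcl2fastq 2.17.1.14 and BWA 0.6.2-r126 on mm10. The deposited values are estimated transcripts, that is expected counts that the authors derived from unique molecular identifier (UMI) counts by a saturation correction. This was checked: undoing the correction gave whole numbers for 100% of values above 0 in every library (largest distance 4.1e-12, tolerance 1e-06). Gene coordinates are GRCm38/mm10 from GENCODE vM21.

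Files held 192 barcode columns, 26559 gene names and 77 ERCC spike-in names over all libraries. Of 4416 wells with cells, 3641 with at least 1000 transcripts were kept, 3457 of them in the 35 haematopoietic libraries; limits of 500 and 2000 were alternatives. No kept cell exceeded 2% of transcripts from Kcnq1ot1. No doublet caller was run. The share of satellite-like gene models differed between libraries and sets, lowest among the haematopoietic groups in CLP, for a cause that was not tested. Gene levels were not tested across sets, except for cultured cells against Flt3pos_mixed and for the difference between the changes of the 2 sets. In an added alternative 8 such models were left out. Markers under the names Lyz2, Hba-a2, Hbb-b1, Hbb-b2, Trbc2, Tpsb2, Ear2, Igj and Sc4mol were not analysed here. Results for some items are not reported here; these items stay in the tests, lists and counts of called genes and are left out of the tallies over named genes.

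Transcripts of kept cells were summed per library and rounded. The 9 comparisons used edgeR 4.0.16 (filterByExpr, TMM, robust quasi-likelihood F tests, Benjamini-Hochberg adjustment over all tested genes, adjusted p at or below 0.05) in R 4.3.3. The first set (LSK, LMPP, CLP and NP1), the second set (IL7rpos, Cd34pos, Flt3pos_mixed and LMPP_gate7) and the cultures were each fitted together, and cultured cells were fitted with Flt3pos_mixed alone. Groups have 2 to 6 libraries, and each comparison has 2 libraries on at least 1 side. LMPP, CLP and Flt3pos_mixed each serve in 2 comparisons and each culture gate in 3, so those results share libraries. The numbers in the library titles were not used as pairs in the reported fits, since the labels do not say what they mark.

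Before the data were examined, 26 gene lists of cell type markers and cell programmes were fixed. Lists with at least 5 tested members were tested by camera of limma 3.58.1 with a preset inter-gene correlation of 0.01, Benjamini-Hochberg adjusted over lists within a comparison, and again with an estimated correlation and by fry. Counts of list genes are given at the adjustment over all genes and adjusted over the list alone.

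Named genes were chosen by a rule also fixed beforehand: up to 10 genes per direction (6 for cultures) with the largest fold change among genes with adjusted p at or below 0.05, at least 50 CPM in the higher group and no overlap of the groups' libraries, leaving out unnamed models, pseudogenes, spike-ins and ribosomal protein genes, and in addition the 5 sort markers and up to 4 members of a described list. By chance alone no overlap would occur in 33.3% of genes for 2 against 2 libraries, in 13.3% for 4 against 2 and in 7.14% for 6 against 2. Where a group had 0 transcripts the fold is a lower limit with 3 counts in that group, and where it had 1 to 3 the ratio is given with an exact 95% counting interval.

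For single cells, UMIs were thinned to 1000 per cell, and a cell was taken as marked by a list when it held at least 3 of its transcripts (2 and 5, and 2000 UMIs, as alternatives). Intervals are exact binomial ones and cover counting error only. Clusters came from 2000 variable genes, 30 principal components, 20 nearest neighbours and Leiden at resolution 1.0 (22 clusters), with 0.6 (17) and 1.5 (24) as alternatives, in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9. The markers were fixed beforehand, but the way clusters were named from them was chosen after the clusters were seen.

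The test was run on simulated data for each comparison, with 200 genes changed 1.5-, 2- or 4-fold. Of genes changed 4-fold 86.4% (Cd34pos versus IL7rpos) to 100% were found, of those changed 2-fold 37.3% (Flt3pos_mixed versus LMPP_gate7) to 88.1%, and of those changed 1.5-fold 6% to 26.9%. False calls were 14 of 149 for LMPP versus LSK and 10 of 111 for culture 18 versus 16. In 20 unchanged simulated lists camera called 0. Alternatives were RLE size factors, DESeq2 1.42.0, no count filter, the cell limits above, thinned cells, replicate blocks, LMPP libraries summed by number and each library left out in turn; uncorrected UMI counts, omission of the satellite-like models, smaller fits, LMPP pairs, removal of erythroid cells, fits with equal cells and transcripts per library and each culture gate against Flt3pos_mixed were added after seeing the data.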

Results

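Single cells sorted from mouse bone marrow, and cells grown from such progenitors for 7 days in culture, were profiled by CEL-Seq2 in 39 libraries. The titles of all culture libraries name Flt3L, that is Flt3 ligand. The marrow came from male C57BL/6J mice of 5 weeks and was depleted of lineage-positive cells. The first set held 2 LSK libraries (Lin- Sca-1 high c-Kit high, 370 cells kept), 4 LMPP libraries (the same gate with Flt3, 748 cells), 2 CLP libraries (Sca-1 low c-Kit low, 370 cells) and 2 NP1 libraries (Sca-1 low or negative, c-Kit low, Flt3 positive, 124 cells). It also held 11 libraries of mixed gates (522 cells). The second set held 2 libraries each of IL7rpos (Il7r positive, Cd34 negative, 192 cells), Cd34pos (Il7r negative, Cd34 positive, 188 cells), Flt3pos_mixed (the Flt3 positive, Sca-1 and c-Kit intermediate gate as a whole, 186 cells) and LMPP_gate7 (Flt3 positive, Sca-1 high, c-Kit high, 190 cells). Cultures gave 2 libraries from each of gates 16, 18 and 17 (190, 190 and 187 cells), and embryonic stem cells gave 4 libraries at falling reaction volumes (44, 47, 48 and 45 cells).

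Depth of the haematopoietic libraries ran from 116146 transcripts in mixed-gate library 6 to 3306645 in LMPP 1_1. Before the saturation correction the median kept cell held 10796 UMIs in LSK, 13841 in LMPP, 4977 in CLP and 10302 in NP1. In the second set it held 5663 in IL7rpos, 5296.5 in Cd34pos, 6652.5 in Flt3pos_mixed and 6495.5 in LMPP_gate7. Cultured cells held 4197.5 UMIs (gate 16), 6416 (gate 18) and 6297 (gate 17). Libraries, not cells, are the replicates below: levels are CPM, that is the transcripts summed over a library's kept cells and scaled to a common total, as mean ± SD over libraries. Adjusted p values of genes come from edgeR quasi-likelihood tests with Benjamini-Hochberg adjustment at 0.05. The labels do not say that replicate libraries came from separate animals or cultures, so these p values measure the spread between these samples. In the second set each IL7rpos, Cd34pos and LMPP_gate7 library has a single number in its title. Both Flt3pos_mixed titles carry both numbers and the word mixed. The Flt3pos_mixed libraries may thus be portions of the same mix, and their spread need not be that between the numbers. The groups, comparisons, gene lists and naming rule were fixed before the data were examined.

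Few genes differed between the LMPP and the LSK gate (4 versus 2 libraries), and those called in this fit were lower in LMPP. The mucin gene Muc13 fell from 101 ± 16.9 to 42.4 ± 7.32 CPM (log2 fold change -1.25, SE 0.17, adjusted p = 0.00128; chromosome 16, 33794037-33819934). Gata2, encoding a transcription factor of stem and early myeloid cells, fell from 105 ± 6.09 to 50.3 ± 3.12 CPM (log2 fold change -1.05, SE 0.17, adjusted p = 0.00983; chromosome 6, 88193891-88207032). The erythroid and megakaryocyte transcription factor gene Gata1 fell by log2 3.31 (SE 0.58, 8 versus 36 transcripts) and the platelet glycoprotein gene Gp5 by log2 3.82 (SE 0.69, 5 versus 33 transcripts), at adjusted p = 0.0203 and 0.0215. Pdzk1ip1 fell by log2 1.19 (14.1 ± 2.62 versus 32.4 CPM, adjusted p = 0.0304).

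Among the sorted surface markers Flt3 stood at 376 ± 44.0 CPM in LMPP and 265 ± 4.14 in LSK (log2 fold change 0.51, SE 0.13) without passing the test (adjusted p = 0.243). Kit, Ly6a, Il7r and Cd34 did not pass it either (0.767, 0.928, 0.746 and 0.746). In all, 9 genes fell and 0 rose of 12015 tested by edgeR; 821 stood below an unadjusted p of 0.05, and DESeq2 called 14 up and 9 down. In simulated data of this shape the same test found 14.9% of genes changed 1.5-fold and 88.1% of genes changed 2-fold. The count came to 1 gene without LSK 1, to 4 without LSK 2 and to 2 without LMPP 1_2. Muc13 lost its call without LSK 2 (log2 fold change -1.07), and Gata2 lost its own without LSK 1 (-1.11), LSK 2 (-0.99) or LMPP 1_2 (-1.02). Gata1, Gp5 and Pdzk1ip1 lost their calls without LSK 1, LSK 2 or LMPP 1_2, and each without at least 1 more LMPP library (Gata1 without 2_2, Gp5 without 1_1, Pdzk1ip1 without 2_1 or 2_2). Over all libraries left out in turn their log2 fold changes ranged from -3.73 to -3.10, from -4.17 to -3.35 and from -1.33 to -1.10.

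The megakaryocyte list as a group was lower in LMPP (1 of 7 genes fell, 6 adjusted over the list alone; camera adjusted p = 7.64e-16, and 0.0758 with an estimated correlation). The erythroid list was lower too (1 of 13 fell, 3 adjusted over the list alone; camera adjusted p = 1.06e-09, and 0.165 with an estimated correlation). So was the multipotent list (2 of 12 fell, 2 adjusted over the list alone; camera adjusted p = 0.000168, and 0.165 with an estimated correlation). Lymphoid progenitor genes were higher in LMPP by the same test (0 of 12 rose, 2 adjusted over the list alone; camera adjusted p = 7.56e-06, and 0.165 with an estimated correlation). Immediate early genes were higher (0 of 13 rose, 9 adjusted over the list alone; camera adjusted p = 1.81e-18, and 0.165 with an estimated correlation). They did so unevenly: against LSK, 12 of 13 rose in LMPP 1_2 and 2_2 and 2 of 12 in LMPP 1_1 and 2_1. Over all tested genes, 64 rose and 46 fell with LMPP 1_2 and 2_2 alone, and 5 rose and 2 fell with LMPP 1_1 and 2_1 alone.

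**Figure D1:**
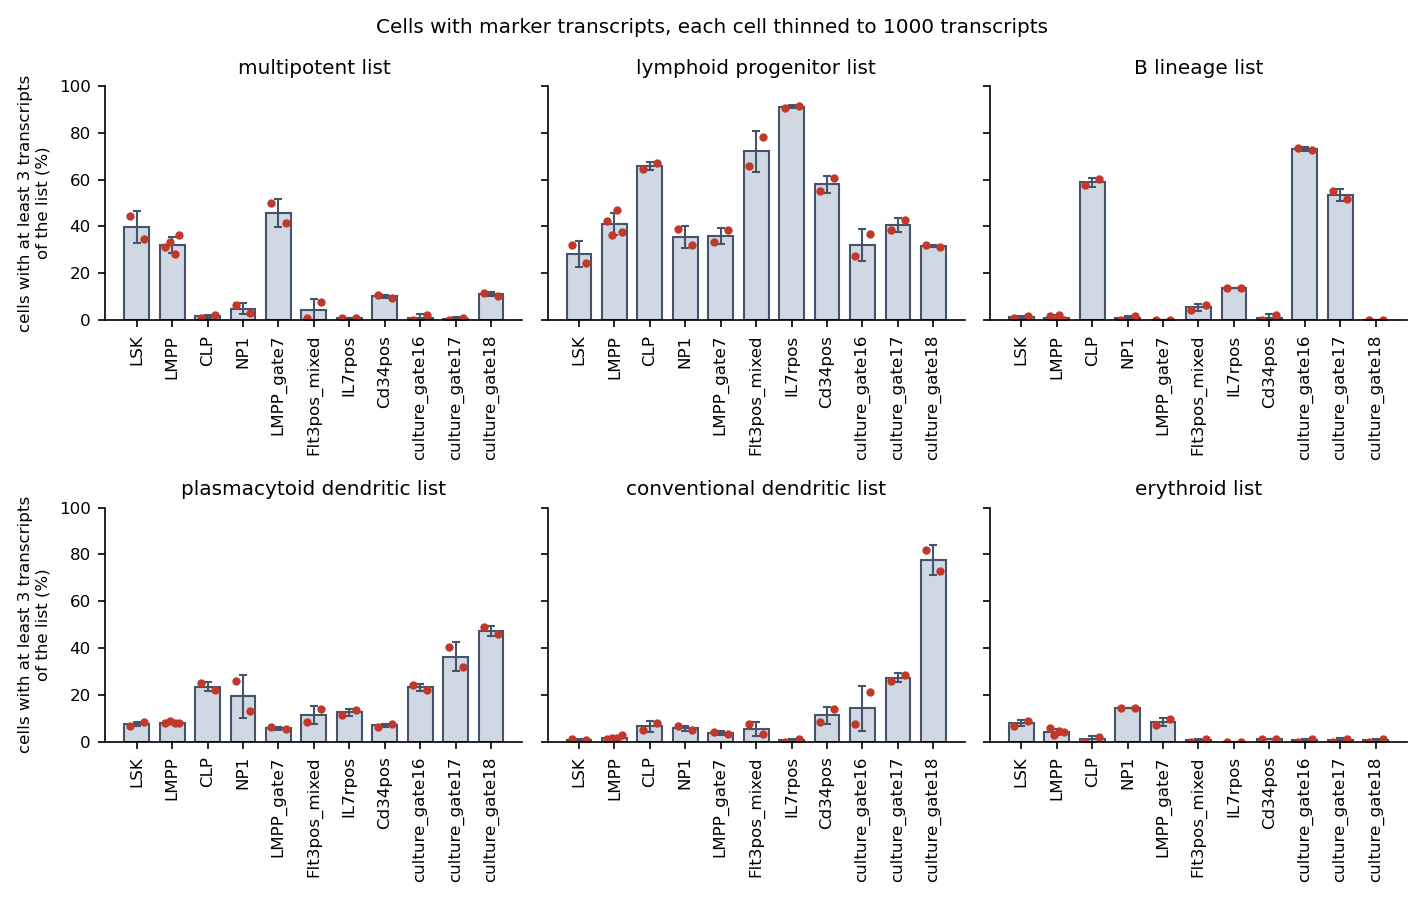
Percent of cells with 3 or more transcripts of a marker list, every cell thinned to 1000 transcripts, for 6 lists in 11 groups. Bars are the mean over libraries, error bars the SD, and red points the single libraries.

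B lineage genes rose and stem cell genes fell between the LMPP and the CLP gate (2 CLP versus 4 LMPP libraries). The surrogate light chain gene Vpreb1 rose 117-fold, from 8.23 ± 8.76 to 1042 ± 51.2 CPM (SE 0.69 log2, adjusted p = 6.26e-04; chromosome 16, 16868403-16870843). Its partner Igll1 rose 102-fold to 1012 ± 88.7 CPM (chromosome 16, 16860671-16863985), and Vpreb3 72.6-fold to 1483 ± 73.1 CPM (chromosome 10, 75943057-75949657). In LMPP Vpreb1 was uneven, at 17.85 and 13.46 CPM in LMPP 1_1 and 2_1 and at 0.713 and 0.889 in LMPP 1_2 and 2_2. With libraries left out in turn the log2 fold change ranged from 6.52 to 7.60 for Vpreb1, from 6.36 to 7.63 for Igll1 and from 5.89 to 6.87 for Vpreb3. With only LMPP 1_1 and 2_1, or only 1_2 and 2_2, all 17 B lineage genes rose (camera adjusted p = 2.69e-89 and 1.17e-129, and 0.0115 and 0.00596 with an estimated correlation). Genes for the transcription factors Spib (140-fold, 82.9 ± 12.9 versus 0.532 CPM, SE 0.47 log2, adjusted p = 7.39e-10; chromosome 7, 44525993-44532071) and Lef1 (117-fold, 194 ± 32.4 versus 1.52 CPM, SE 0.36 log2, adjusted p = 5.73e-10; chromosome 3, 131110471-131224356) rose as well. Among the genes the naming rule allows, Prss34 rose most, a basophil protease gene (305-fold, 233 ± 136 versus 0.705 CPM, SE 0.64 log2, adjusted p = 1.4e-04; chromosome 17, 25298394-25300165). The granzyme gene Gzma, of cytotoxic lymphocytes, rose 122-fold to 62.8 ± 17.2 CPM (chromosome 13, 113093825-113100981).

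On the other side, the stem cell transcription factor gene Hlf fell 40.2-fold, from 369 ± 44.2 to 10.5 ± 11.6 CPM (SE 0.64 log2, adjusted p = 0.00109; chromosome 11, 90336536-90390895). Vldlr, a lipoprotein receptor gene, gave 3 transcripts in CLP against 1046 in LMPP, a 68.6-fold fall (counting interval 23.4 to 333; chromosome 19, 27216484-27254231). For Hlf the log2 fold change was -7.24 without CLP 1 and -4.29 without CLP 2, and for Vldlr -10.56 without CLP 2. The adhesion receptor gene Adgrl4 fell 8.58-fold (50.5 ± 3.08 versus 432 ± 27.8 CPM; chromosome 3, 151437887-151545086). Of the surface markers, Il7r rose 6.65-fold (239 ± 29.5 versus 35.3 CPM, adjusted p = 0.0034). Cd34 (5.98-fold), Kit (4.31-fold), Ly6a (3.37-fold) and Flt3 (2.29-fold, 164 ± 14.5 versus 376 CPM, adjusted p = 1.11e-06) fell.

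Across 12015 genes 1665 rose and 1439 fell by edgeR, with 4397 below an unadjusted p of 0.05, and DESeq2 called 1338 up and 914 down. All 17 B lineage genes tested rose, Cd79b by 10.7-fold to 463 ± 42.0 CPM and Bst1 by 53.7-fold (camera adjusted p = 1.52e-33). Of 12 multipotent genes 11 fell (12 adjusted over the list alone), among them Meis1 by 5.12-fold. The T, NK and innate lymphoid list rose in 13 of 16 genes (13 adjusted over the list alone), Thy1 by 8.42-fold, and the basophil and mast list in 5 of 5, Mcpt8 by 42.6-fold. In the plasmacytoid dendritic list 8 of 17 genes rose and 1 fell (10 and 1 adjusted over the list alone), with Siglech up 8.88-fold to 108 ± 5.14 CPM. Each of these lists held with an estimated correlation (camera adjusted p = 0.0157), but with only 1 of the LMPP pairs the multipotent list did not (0.058 and 0.056). For the T, NK and innate lymphoid, the basophil and mast and the plasmacytoid dendritic list, fits with single LMPP pairs were not examined. Summed libraries do not show how many cells carry a rise. By Leiden clusters, CLP cells made up 4.76% of 105 basophil and mast-like cells and 44.6% of 74 T, NK and innate lymphoid-like cells. A small part of the 370 CLP cells may thus carry the rises of these 2 lists, of Prss34 and of Gzma. The G2/M list rose in 22 of 22 genes (camera adjusted p = 9.93e-18, and 0.155 with an estimated correlation), Ccnb2 by 4.73-fold, Birc5 by 3.96-fold and Mki67 by 3.12-fold. S phase genes rose in 11 of 22 (13 adjusted over the list alone; camera adjusted p = 6.27e-06, and 0.314 with an estimated correlation), Uhrf1 by 2.49-fold and Pcna by 2.34-fold. Without CLP 2 the count of called genes was 1514. Satellite-like gene models held 0.33 to 1.34% of transcripts in CLP libraries and 2.23 to 4.47% in LMPP libraries, and 3100 genes were called with these models left out. One of them, Gm10800, held 0.0084 to 0.0140% in CLP and 1.51 to 3.53% in LMPP libraries. A technical difference of the CLP libraries is thus not excluded.

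Erythroid genes such as Klf1 were higher and B lineage genes such as Igll1 lower in NP1 than in CLP (2 versus 2 libraries). The erythroid transcription factor gene Klf1 rose 17.2-fold, from 4.87 to 95.2 ± 48.8 CPM (SE 0.50 log2, adjusted p = 5.96e-06; chromosome 8, 84901928-84905291). Ermap, an erythroid membrane protein gene, rose 27.4-fold to 141 ± 85.1 CPM (SE 0.45 log2, adjusted p = 2.33e-07; chromosome 4, 119175457-119190011) and the water channel gene Aqp1 23.7-fold to 153 ± 58.7 CPM (SE 0.43 log2, adjusted p = 2.44e-07; chromosome 6, 55336432-55348555). Gata1 rose 15.2-fold. Igll1 fell from 2190 transcripts to 1 (1600-fold, counting interval 287 to 63200, adjusted p = 0.0056) and Prss34 from 539 to 0 (at least 131-fold). As above, a small part of the CLP cells may carry the Prss34 transcripts. The transcription factor gene Lef1 fell 155-fold (42.6 to 1280).

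Flt3 rose 1.72-fold (283 ± 40.7 versus 164 CPM, adjusted p = 0.00178), Kit 2.69-fold and Cd34 3.04-fold (247 ± 76.0 versus 80.4 CPM). Ly6a fell 4.54-fold, and Il7r did not pass (log2 fold change -1.58, adjusted p = 0.0986). Prtn3, a granule protease gene, rose 12.9-fold (261 ± 80.9 CPM), F13a1 6.21-fold (115 ± 14.8 CPM) and the macrophage growth factor receptor gene Csf1r 5.11-fold (128 ± 72.1 CPM). The neutrophil list was not called (3 of 13 rose; camera adjusted p = 0.266). Satellite-like gene models held 7.18 to 7.45% of transcripts in NP1 libraries and 0.33 to 1.34% in CLP libraries. For Gm10800 alone the shares were 5.70 to 5.80% and 0.0084 to 0.0140%, so a technical difference of the CLP libraries is not excluded here either. In all 924 genes rose and 1228 fell by edgeR, with 3740 below an unadjusted p of 0.05, and DESeq2 called 596 and 926. Of the B lineage list 16 of 17 genes fell (17 adjusted over the list alone; camera adjusted p = 4.64e-23, and 0.0979 with an estimated correlation). Of the T, NK and innate lymphoid list 13 of 16 fell, Thy1 by 18.5-fold (14 adjusted over the list alone; 3.72e-15 by camera, and 0.0673 with an estimated correlation). Erythroid genes rose in 9 of 13 (9 adjusted over the list alone; camera adjusted p = 7.21e-13, and 0.0774 with an estimated correlation). Monocyte and macrophage genes rose in 4 of 12 (8 up and 1 down adjusted over the list alone; camera adjusted p = 2.84e-05, and 0.364 with an estimated correlation). With the 18 NP1 and 4 CLP cells that held 3 or more erythroid transcripts removed, a step chosen after seeing the data, 747 genes rose and 1160 fell, with 5 of 9 erythroid genes up (camera adjusted p = 7.84e-05, and 0.0949 with an estimated correlation) and 15 of 17 B lineage genes down.

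Within the second set, Clec9a and Ms4a2 stood on the Cd34pos side and B lineage genes on the IL7rpos side (2 versus 2 libraries). Clec9a, a lectin of type 1 conventional dendritic cells, gave 74 transcripts in Cd34pos and 0 in IL7rpos (72.7 ± 23.2 CPM, at least 27.1-fold; chromosome 6, 129408862-129424763). Plbd1 gave 107 and 0 (at least 39.2-fold; chromosome 6, 136612070-136661928). The basophil and mast cell receptor gene Ms4a2 gave 61 and 0 (at least 22.4-fold), and Gata2 gave 92 and 1 (101-fold, counting interval 17.7 to 4040; chromosome 6, 88193891-88207032). Rag1, of the antigen receptor recombinase, fell 16.7-fold (17.9 ± 11.97 versus 297 ± 1.48 CPM, SE 0.31 log2, adjusted p = 8.1e-13; chromosome 2, 101638282-101649501). The B lineage transcription factor genes Ebf1 (12.8-fold, 265 ± 110 CPM in IL7rpos, SE 0.42 log2, adjusted p = 8.77e-05; chromosome 11, 44617317-45008091) and Pax5 (13.9-fold; chromosome 4, 44524757-44710487) fell, and Vpreb3 fell 34.4-fold.

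The sorted markers Il7r and Cd34 differed in the direction of the gates. Il7r fell 6.68-fold (55.4 ± 3.93 versus 372 ± 79.6 CPM, adjusted p = 2.74e-09). Cd34 rose 2.04-fold (365 ± 57.7 versus 178 ± 44.3 CPM, adjusted p = 4.63e-04), a call lost without IL7rpos WT3615 (log2 fold change 0.80). Kit rose 2.03-fold (208 ± 24.7 versus 102.4 CPM), while Flt3 (593 ± 74.5 versus 592 ± 0.599 CPM, adjusted p = 0.997) and Ly6a (0.994) did not pass. By edgeR 194 genes rose and 189 fell of 8024 tested; 1157 stood below an unadjusted p of 0.05, and DESeq2 called 62 and 50. B lineage genes fell in 11 of 12 (12 adjusted over the list alone; camera adjusted p = 8.63e-45, and 0.0112 with an estimated correlation). Conventional dendritic genes rose in 7 of 11, Xcr1 by 11.7-fold (10 adjusted over the list alone; camera adjusted p = 1.04e-29, and 0.0491 with an estimated correlation). Of the basophil and mast list 3 of 6 rose (6 adjusted over the list alone; camera adjusted p = 2.33e-14, and 0.0741 with an estimated correlation). S phase genes fell in 6 of 21 (14 adjusted over the list alone; camera adjusted p = 2.82e-12, and 0.0741 with an estimated correlation). G2/M genes fell in 8 of 22, Cdk1 by 3.13-fold (12 adjusted over the list alone; 1.42e-12 by camera, and 0.169 with an estimated correlation). The count of calls was 163 without IL7rpos WT3615 and 254 without Cd34pos WT3615. The wells of these groups lay in different barcode ranges; between such ranges within 5 other groups, 10 of 8639 genes were called.

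Lymphoid genes were higher and stem cell genes lower in Flt3pos_mixed than in LMPP_gate7 (2 versus 2 libraries). As the Flt3pos_mixed libraries may be portions of the same mix, the p values here may understate the spread between separate samples. Il7r rose 13.6-fold, from 13.8 ± 11.6 to 188 ± 24.0 CPM (SE 0.32 log2, adjusted p = 7.77e-10; chromosome 15, 9505788-9530176), and Ebf1 27.7-fold to 125 ± 47.5 CPM (SE 0.56 log2, adjusted p = 9.77e-05). Rag1 rose 12.5-fold to 101.7 ± 20.1 CPM, and Dntt, of the template-free DNA polymerase of lymphocytes, 4.53-fold to 2263 ± 875 CPM. With libraries left out in turn the log2 fold change ranged from 3.08 to 5.01 for Il7r, from 4.34 to 5.31 for Ebf1 and from 3.09 to 4.52 for Rag1. The stem cell factor gene Mecom fell 13.4-fold (chromosome 3, 29951296-30548008), Hlf 14.8-fold (38.8 ± 21.5 versus 565 ± 132 CPM), Gata2 6.08-fold and Kit 2.64-fold (adjusted p = 1.71e-06). For Mecom the log2 fold change ranged from -5.31 to -2.95 with libraries left out in turn, and for Hlf from -4.58 to -3.39. Flt3 (adjusted p = 0.283), Cd34 (0.104) and Ly6a (0.407) did not pass; for Ly6a the log2 fold change was -1.38, and -3.10 without Flt3pos_mixed 2.

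By edgeR 182 genes rose and 160 fell, with 1190 below an unadjusted p of 0.05, and DESeq2 called 57 and 33. Multipotent genes fell in 10 of 12 (12 adjusted over the list alone; camera adjusted p = 1.34e-34) and B lineage genes rose in 6 of 12, Blnk by 10.3-fold (10 adjusted over the list alone; 2.59e-18), both at camera adjusted p = 0.0301 with an estimated correlation. Lymphoid progenitor genes rose in 5 of 12 (6 up and 1 down adjusted over the list alone; camera adjusted p = 1.62e-13, and 0.0793 with an estimated correlation). Plasmacytoid dendritic genes rose in 2 of 11 (camera adjusted p = 0.000173, and 0.0793 with an estimated correlation). The count was 124 without LMPP_gate7 WT3615 and 179 without LMPP_gate7 WT3616. Beside CLP versus LMPP, which shares no library with this comparison, 106 genes rose in both (29.5 by chance), 123 fell in both (21 by chance) and 17 went opposite ways, among 8008 genes tested in both.

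**Figure D2:**
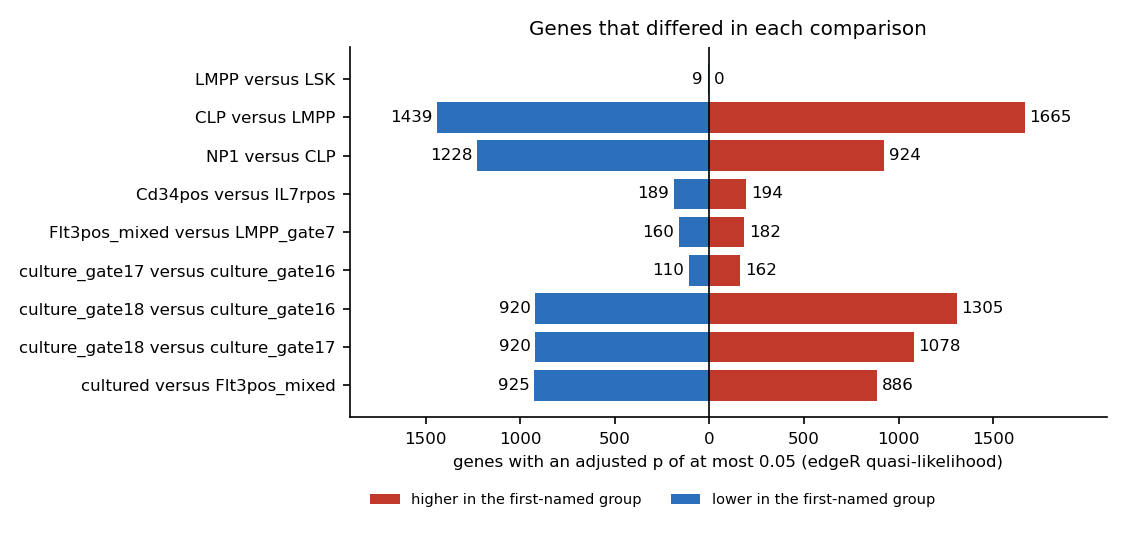
Genes called up and down in each comparison by edgeR quasi-likelihood tests with Benjamini-Hochberg adjusted p at or below 0.05.

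The share of single cells marked by these lists depended on depth, and shares from both sets stand side by side as description. With every cell thinned to 1000 UMIs, 58.9 ± 1.85% of CLP cells held 3 or more B lineage transcripts (82.7% unthinned). The share was 13.5 ± 0% of IL7rpos (26 of 192 cells; 47.9% unthinned), 5.39 ± 1.60% of Flt3pos_mixed (20.99% unthinned) and 1.06% of Cd34pos (6.38% unthinned). It was 0.937% of LMPP (22.2% unthinned) and 0 of 190 LMPP_gate7 cells (6.86% unthinned), so the order of LMPP and Flt3pos_mixed turns with depth. Embryonic stem cells gave 6.52% (12 of 184, interval 3.41 to 11.1), and the thinned shares of Flt3pos_mixed, Cd34pos, LMPP and LMPP_gate7 lie below that value. Which list genes marked the embryonic stem cells was not tested. Their share may thus hold true expression of list genes and is not a measure of background alone. Lymphoid progenitor transcripts marked 91.2 ± 0.743% of IL7rpos, 72.1 ± 8.70% of Flt3pos_mixed, 65.9 ± 1.79% of CLP and 58.0 ± 3.76% of Cd34pos cells, and 0 of 184 embryonic stem cells. Unthinned, the same 4 groups gave 100, 97.86, 97.84 and 95.22%, with LSK at 95.59% and LMPP at 97.86%, so these shares hardly part the groups at full depth. Multipotent transcripts marked 45.8 ± 6.02% of LMPP_gate7 (95.3% unthinned), 39.6 ± 6.81% of LSK (95.05% unthinned), 32.2 ± 3.40% of LMPP (96.4%), 10.1 ± 0.754% of Cd34pos (60.6%) and 1.62 ± 0.752% of CLP cells (12.4%), with 3.80% in embryonic stem cells (7 of 184).

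Conventional dendritic transcripts marked 11.2 ± 3.76% of Cd34pos (38.8% unthinned) and 0.521 ± 0.737% of IL7rpos cells (19.3% unthinned). Plasmacytoid dendritic transcripts marked 23.5 ± 2.09% of CLP (70.8% unthinned) and 12.5% of IL7rpos cells (91.7% unthinned), an order that turns with depth. Erythroid transcripts marked 14.5 ± 0% of NP1 (18 of 124; 63.7% unthinned) and 1.08 ± 1.52% of CLP cells (10.5% unthinned). They also marked 29 of 370 LSK, 32 of 748 LMPP and 16 of 190 LMPP_gate7 cells (74.4, 74.7 and 60.9% unthinned). Embryonic stem cells gave 0 of 184 for each of these lists. Permutation of 2 against 2 libraries cannot give a p below 0.33, so these shares carry no p value. By Leiden clusters named from the fixed markers, 47.6 ± 1.17% of CLP cells were B lineage-like, 68.8 ± 13.3% of IL7rpos cells lymphoid progenitor-like and 60.1 ± 8.34% of LMPP_gate7 cells multipotent-like. At resolution 0.6 these shares were 61.9, 69.8 and 0.521%, so the last of them rests on the resolution. The clusters also kept CLP cells apart from other groups. At resolution 1.0 CLP cells made up 0.375% of 267 lymphoid progenitor-like cells, though lymphoid progenitor transcripts marked most CLP cells. Of the B lineage-like clusters they made up 80, 84.8, 0 and 1.01%. Set and cell type thus cannot be told apart in the clustered shares of CLP and IL7rpos.

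Of the 3 culture gates, gate 16 and gate 17 both held cells with B lineage transcripts, and gate 17 had fewer transcripts of Vpreb3 and Ebf1 and more of Ly6a (2 versus 2 libraries). Vpreb3 fell 4.54-fold from gate 16 to gate 17 (475 ± 6.23 versus 2156 ± 0.4001 CPM, SE 0.16 log2, adjusted p = 2.77e-13), Cd79b fell 2.65-fold and the B lineage transcription factor gene Ebf1 2.04-fold. Ly6a rose 5.58-fold (72.4 ± 0.202 versus 12.96 ± 6.66 CPM, SE 0.39 log2, adjusted p = 9.6e-05), and so did the interferon-stimulated genes Rtp4 (8.01-fold) and Mx1 (6.33-fold) and the hexokinase gene Hk2 (5.18-fold). Cd34 rose 4.80-fold (51.8 ± 16.5 versus 10.5 ± 8.54 CPM), a call lost without culture 16 library 1 (log2 fold change 1.66); Flt3 did not pass (log2 fold change 0.86, adjusted p = 0.118). B lineage genes fell in 8 of 17 (12 adjusted over the list alone; camera adjusted p = 9.86e-16, and 0.165 with an estimated correlation). Interferon-stimulated genes rose in 6 of 19 (12 adjusted over the list alone; camera adjusted p = 4.05e-09, and 0.165 with an estimated correlation). Glycolysis genes rose in 4 of 13 (5 adjusted over the list alone; camera adjusted p = 0.00022, and 0.165 with an estimated correlation). By edgeR 162 genes rose and 110 fell (131 and 135 with RLE scaling), with 1244 below an unadjusted p of 0.05, and DESeq2 called 55 and 40. The count was 115 without culture 16 library 1, 161 without culture 17 library 3, 88 without culture 17 library 4, 84 with cells thinned to 1000 transcripts and 255 without satellite-like gene models. Such models held 24.6 to 27.1% of transcripts in gate 16, 17.2 to 17.6% in gate 17 and 18.5 to 21.5% in gate 18, and median genes per cell averaged 1472, 2176 and 2132. The mitochondrial ribosomal RNA genes mt-Rnr2 (log2 fold change -0.69, adjusted p = 4.59e-04) and mt-Rnr1 (-0.60, adjusted p = 0.01135) were lower in gate 17. How far cell quality differs between these gates was not tested.

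Genes such as Csf1r and Aldoa were higher, and all B lineage genes of the list lower, in gate 18 than in gate 16 (2 versus 2 libraries). Csf1r rose 28.5-fold (552 ± 2.26 versus 19.1 CPM), the chemokine receptor gene Ccr2 15.0-fold (1838 ± 78.2 versus 122 CPM) and the aldolase gene Aldoa 10.1-fold (1414 ± 3.18 versus 140 ± 17.4 CPM). The interferon-inducible gene Ifi204 gave 128 transcripts against 0 (at least 32.2-fold) and the Fc receptor gene Fcgr3 rose at least 26.7-fold. Mzb1, a chaperone gene of antibody-secreting and B cells, gave 0 transcripts against 309 (at least 136-fold), Vpreb1 2 against 1026 (680-fold, counting interval 188 to 5620). Ebf1 fell 72.2-fold. Ly6a rose 26.3-fold (343 ± 91.1 versus 12.96 CPM), Cd34 8.72-fold and Flt3 4.06-fold (226 ± 35.3 versus 55.1 CPM). Il7r fell 3.22-fold, and Kit did not pass (log2 fold change 1.19, adjusted p = 0.0719; 2.81 without culture 16 library 2). By edgeR 1305 genes rose and 920 fell, with 2950 below an unadjusted p of 0.05, and DESeq2 called 626 and 345. All 17 B lineage genes fell (camera adjusted p = 1.66e-76, and 0.0186 with an estimated correlation). Glycolysis genes rose in 12 of 13 (13 adjusted over the list alone; camera adjusted p = 4.25e-19, and 0.0452 with an estimated correlation). Monocyte and macrophage genes rose in 9 of 11 (10 adjusted over the list alone; 2.91e-18 by camera, and 0.105 with an estimated correlation). Interferon-stimulated genes rose in 18 of 19 (18 adjusted over the list alone; camera adjusted p = 1.02e-11, and 0.122 with an estimated correlation). Conventional dendritic genes rose in 5 of 14 (5 adjusted over the list alone; camera adjusted p = 2.82e-05, and 0.379 with an estimated correlation). The plasmacytoid dendritic list was not called (6 of 18 rose and 2 fell), and its member Spib fell 5.35-fold. S phase genes fell in 18 of 21 (18 adjusted over the list alone; 5.22e-10 by camera, and 0.122 with an estimated correlation).

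Against gate 17 (2 versus 2 libraries), gate 18 gained the matrix gene Fn1 (195 transcripts against 0, at least 71.7-fold, 157 CPM; chromosome 1, 71585520-71653200) and the lectin genes Clec10a (88.0-fold, 308 ± 68.2 CPM) and Mgl2 (at least 29.1-fold). Csf1r rose 13.1-fold, Ccr2 10.7-fold, Aldoa 7.18-fold and Ly6a 4.72-fold, whereas Clec9a fell by log2 2.73 and Cd79a fell 103-fold. Clec10a gave only 5 transcripts in gate 17, and its log2 fold change ranged from 5.459 to 10.5 with libraries left out in turn. For Clec9a this range was -4.255 to -1.957 and for Cd79a -7.654 to -6.069. Flt3 rose 2.23-fold, a call lost without culture 17 library 3 (log2 fold change 0.75). By edgeR 1078 genes rose and 920 fell, with 2807 below an unadjusted p of 0.05, and DESeq2 called 385 and 283. The count was 1324 without culture 18 library 1 and 1317 without culture 17 library 4. B lineage genes fell in 17 of 17 (camera adjusted p = 2.38e-66, and 0.0306 with an estimated correlation) and glycolysis genes rose in 13 of 13 (1.87e-17, and 0.0447 with an estimated correlation). Monocyte and macrophage genes rose in 9 of 11 (10 adjusted over the list alone; camera adjusted p = 4.77e-20, and 0.087 with an estimated correlation).

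B lineage transcripts marked 73.2 ± 0.743% of gate 16 cells (84.2% unthinned), 53.4 ± 2.52% of gate 17 (74.8% unthinned) and 0 of 190 gate 18 cells (9.97% unthinned). Monocyte and macrophage transcripts marked 57.4 ± 1.38% of gate 18, 15.0 ± 0.566% of gate 17 and 5.79 ± 2.23% of gate 16 cells (95.2, 32.0 and 15.8% unthinned). Conventional dendritic transcripts marked 77.4 ± 6.36%, 27.3 ± 1.79% and 14.2 ± 9.68% (100, 83.8 and 46.8% unthinned). Plasmacytoid dendritic transcripts were present in each gate, at 47.4 ± 2.20% of gate 18, 36.2 ± 6.19% of gate 17 and 23.2 ± 1.49% of gate 16 cells (95.3, 88.9 and 74.2% unthinned). Members of this list did not move together: Cybb stood at 1118 CPM in gate 18 and 177 in gate 16, Spib at 58.3 and 314. These shares thus do not show that the marked cells are plasmacytoid dendritic cells.

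Cultured cells as a whole (6 libraries) held more transcripts of genes such as Spib and Siglech than the uncultured Flt3pos_mixed cells (2 libraries), and fewer of stem cell genes such as Meis1. Spib gave 819 transcripts against 1 (304-fold, counting interval 54.4 to 12000), the plasmacytoid dendritic lectin gene Siglech rose 35.0-fold (249 ± 52.7 versus 6.76 CPM) and Id3, an inhibitor of E proteins, rose 128-fold (35.4 to 1060). Adgrl4 fell 58.6-fold (1.54 versus 102 ± 18.8 CPM, SE 0.40 log2, adjusted p = 1.1e-13) and Cd27 15.9-fold. Cd34 fell 7.09-fold, Dntt 6.95-fold, Kit 5.01-fold and Flt3 4.35-fold. The homeobox genes Meis1 and Hoxa9 fell 13.8-fold and 13.4-fold. Il7r (log2 fold change 0.01, adjusted p = 0.982) and Ly6a (0.56, adjusted p = 0.656; -0.25 without Flt3pos_mixed 1 and 2.26 without Flt3pos_mixed 2) did not pass. By edgeR 886 genes rose and 925 fell of 8132 tested, with 2797 below an unadjusted p of 0.05, and DESeq2 called 410 and 290. Plasmacytoid dendritic genes rose in 16 of 18 (16 adjusted over the list alone; camera adjusted p = 2.38e-21), and B lineage genes in 15 of 17 (16 adjusted over the list alone; 8.1e-10). Sterol synthesis genes rose in 12 of 14, Msmo1 by 4.71-fold (12 adjusted over the list alone; camera adjusted p = 6.18e-07). All 3 lists stood at camera adjusted p = 0.0595 with an estimated correlation. Multipotent genes fell in 5 of 7 (5 adjusted over the list alone; camera adjusted p = 3.24e-07, and 0.0595 with an estimated correlation). Nucleolar genes fell in 14 of 17 (16 adjusted over the list alone; 1.59e-08 by camera, and 0.198 with an estimated correlation). Each gate was also set against Flt3pos_mixed in this fit, a step chosen after seeing the data. B lineage genes rose in 17 of 17 in gate 16 (camera adjusted p = 9.78e-118, and 0.00282 with an estimated correlation) and in 17 of 17 in gate 17 (3.45e-87 and 0.00694), while in gate 18 2 rose and 9 fell (0.00408 and 0.176). Plasmacytoid dendritic genes rose in 12, 14 and 15 of 18 in gates 16, 17 and 18 (camera adjusted p = 6.45e-16, 7.56e-23 and 1.28e-13, and 0.126, 0.0788 and 0.125 with an estimated correlation). Culture, Flt3L, time and batch cannot be told apart here. The Flt3pos_mixed libraries may be portions of the same mix, so these p values too may understate the spread between separate samples.

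Embryonic stem cells at smaller reaction volumes gave fewer transcripts and slightly fewer genes per cell (1 library per volume, so no test was made and volume cannot be told apart from library). Median transcripts per cell were 57935 at full volume, 45444 at 5-fold, 39366 at 7-fold and 33237 at 10-fold reduction, ratios to full volume of 0.784, 0.679 and 0.574. The lower quartile was 42692 at full volume, 29613 at 5-fold, 3946 at 7-fold and 3807.5 at 10-fold reduction. With wells under 2000 transcripts left out the medians were 59290, 47674, 39491 and 38678, so such wells lowered the 10-fold median but hardly the 7-fold one. At 7-fold this limit kept 46 of 48 wells, with a lower quartile of 3946 before it. Poor wells above the limit thus stayed in, and their effect on the 7-fold median was not tested. Median genes were 7392.5, 6834, 6411.5 and 6224, and with every cell thinned to 2000 transcripts 1184.5, 1184, 1143 and 1159. CPM over 3339 genes correlated with full volume at r = 0.978, 0.97 and 0.968, and 26 genes (0.779%) differed over 2-fold between full volume and 10-fold reduction. The nodal antagonist gene Lefty2 went from 105 CPM (counting interval 92.9 to 119) to 31.6 (23.1 to 42.3), and the histone gene H3f3a from 38.0 (30.8 to 46.5) to 127 (109 to 147). The pluripotency gene Nanog stood at 275.8, 297.2, 269.4 and 304.4 CPM, and Pou5f1 at 837.8, 652.3, 658.1 and 697.3.

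**Figure D3:**
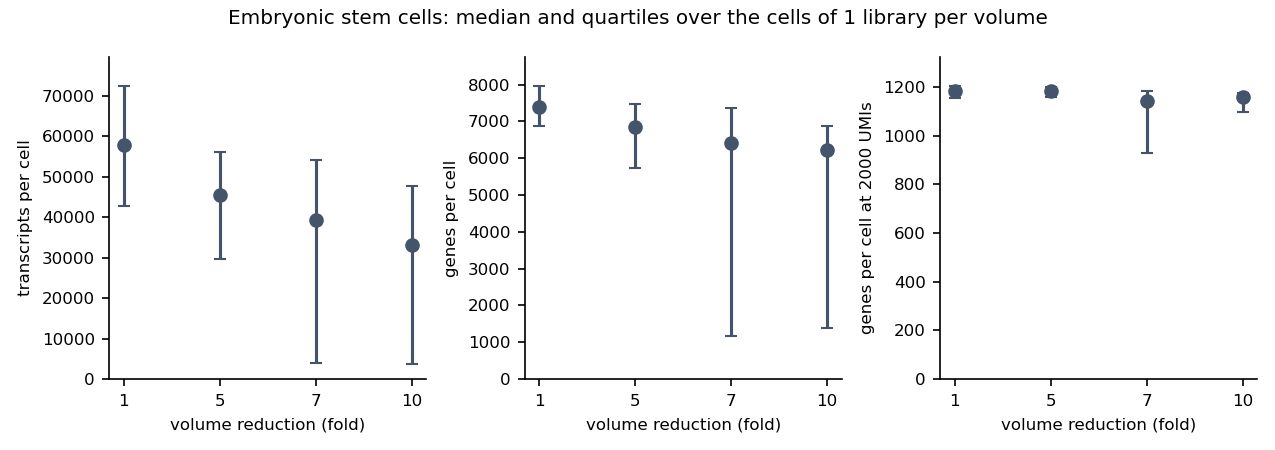
Transcripts, genes, and genes at 2000 transcripts per embryonic stem cell against the fold of volume reduction. Points are medians and bars the quartiles, for 1 library per volume.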

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

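Values in this part were set apart by rules fixed for all results, and no explanation is offered for them. In LMPP, Igkc stood at 2.48 CPM in LMPP 2_1 against 0.298, 0 and 0 in LMPP 1_1, 1_2 and 2_2, a Dixon ratio of 0.88; 38 such fields were compared, and about 1 in 20 passes by chance.

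The change from the higher to the lower Sca-1 and c-Kit gate differed between the first set (CLP versus LMPP) and the second set (Flt3pos_mixed versus LMPP_gate7) for 420 of 10436 genes by edgeR quasi-likelihood tests with Benjamini-Hochberg adjustment, 211 larger and 209 smaller in the first set. As the gates and the batches both differ between the sets, the cause was not tested. Differences of the log2 changes, first minus second set, were -2.42 for Rab38 (adjusted p = 0.0446), -1.56 for Gcnt2 (0.0146), -1.90 for Acot1 (0.0157), -1.51 for Angpt1 (0.00325) and -1.51 for Adgrl4 (4.4e-04). For the sort markers they were -1.61 for Flt3 (adjusted p = 1.31e-04) and -2.08 for Cd34 (1.58e-06). The sort markers Kit (-0.73, adjusted p = 0.171), Il7r (-1.07, 0.685) and Ly6a (-0.40, 0.848) did not pass.

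The 11 mixed-gate libraries, which enter no comparison, held cells of several lineages; the highest share of cells with 3 or more transcripts of a list, at 1000 UMIs per cell, is given with its 95% interval. B lineage transcripts reached 51.47% (35 of 68 cells, 39.0 to 63.8) and T, NK and innate lymphoid transcripts 26.47% (18 of 68, 16.5 to 38.6), both in library 2. Plasmacytoid dendritic transcripts reached 58.82% in library 11 (20 of 34, 40.7 to 75.3), conventional dendritic ones 30.49% in library 4 (25 of 82, 20.8 to 41.6) and erythroid ones 38.46% in library 5 (10 of 26, 20.2 to 59.4). Neutrophil transcripts reached 17.14% in library 8 (6 of 35, 6.56 to 33.6), basophil and mast ones 17.65% in library 6 (3 of 17, 3.80 to 43.4) and plasma cell ones 19.35% in library 9 (6 of 31, 7.45 to 37.5).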

How the results depend on the processing

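Over 535 named-gene results, 8061 values under alternatives left 7505 the same, 513 weaker, 24 stronger and 19 reversed. RLE size factors weakened 1 of 535, no count filter 18 of 535, DESeq2 72 of 510, thinning to 1000 transcripts per cell 85 of 353 and leaving out a library 307 of 2667. Called genes for LMPP versus LSK numbered 9 as reported, 114 with no count filter, 2 thinned, 23 by DESeq2, 27 with a replicate block (16 in the same fit with no block), 32 with LMPP libraries summed by number, 110 with LMPP 1_2 and 2_2 alone, and 1 to 13 without single libraries. They numbered 777 thinned and 1514 to 2946 without single libraries for CLP versus LMPP, and 418 thinned for NP1 versus CLP. Cd34pos versus IL7rpos gave 73 thinned, 112 by DESeq2 and 163 to 305 without single libraries, and Flt3pos_mixed versus LMPP_gate7 75, 90 and 124 to 379. Culture 17 versus 16 gave 84 thinned, 95 by DESeq2 and 88 to 372 without single libraries, culture 18 versus 16 gave 632 and 971, culture 18 versus 17 gave 447, 668 and 1317 to 1558, and cultured versus Flt3pos_mixed gave 358, 700 and 1159 to 1872. Thinning leaves fewer genes to test; the cause of the other moves was not tested. A replicate block gave 3420 calls for CLP versus LMPP, 475 for Cd34pos versus IL7rpos and 1683 for culture 18 versus 16. Deviations of libraries with the same number correlated by 0.126 to 0.254 in the first set, 0.021 to 0.15 in the second and -0.047 in the cultures, with only 2 numbers per group. Of 173 tests of fixed gene lists, 100 were called by camera at the preset correlation, 14 with an estimated correlation and 75 by fry.

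Turned directions, as log2 fold changes, lay near 0 for most: LMPP versus LSK: Ly6a thinned -0.0591; NP1 versus CLP: Xaf1 thinned 0.38. Cd34pos versus IL7rpos: Flt3 gave -0.00854 with no filter, -0.17 thinned, -0.00699 by DESeq2 and -0.14 to 0.13 with libraries left out. Cd34pos versus IL7rpos: Ly6a gave -0.00906 at 2000 transcripts per well and -0.0785 to 0.12 with libraries left out. Cd34pos versus IL7rpos: Gcnt2 gave -0.46 thinned and Cd34pos versus IL7rpos: Ssr2 -0.0522 thinned. With libraries left out, cultured versus Flt3pos_mixed: Ly6a gave -0.25 to 2.26 and cultured versus Flt3pos_mixed: Il7r -0.12 to 0.13 (-0.0513 with no filter, -0.00185 at 2000 transcripts per well). Thinned, cultured versus Flt3pos_mixed: Mki67 gave -0.0258. By fry the neutrophil list in Flt3pos_mixed versus LMPP_gate7 (adjusted p = 0.976) and the G2/M list in culture 17 versus 16 (0.911) turned direction.

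In cells with marker transcripts: B lineage in CLP stood at 65.4% with 2 or more transcripts, 55.1% with 5 or more, 63.4% at 2000 UMIs and 82.7% not thinned, against 58.9% as reported. For cells with marker transcripts: B lineage in culture_gate16 the same were 77.4, 68.4, 79.2 and 84.2%, and 76.2% without satellite-like models. The share of conventional dendritic in Cd34pos was 17.4% at 2000 UMIs and 38.8% not thinned, of erythroid in NP1 63.7% not thinned, and of multipotent in LMPP_gate7 65.2, 17.4, 67.2 and 95.3%. At resolution 0.6, B lineage-like cells made up 61.9% of CLP and multipotent-like cells 0.521% of LMPP_gate7. Genes per embryonic stem cell at 10-fold relative to full volume had a ratio of 0.978 thinned to 2000.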

Other observations

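The tests in this part were all chosen after the results were seen, with bounds set then. Within LMPP, the libraries numbered 2 held more immediate early transcripts than those numbered 1: 11 of 13 genes of the list rose (camera adjusted p = 4.3e-80, and 3.57e-04 with an estimated correlation), Nr4a1 by log2 3.88 and Fos by log2 2.18. Cells with 3 or more such transcripts at 1000 per cell made up 26.9 and 29.8% of LMPP 1_2 and 2_2, and 5.29 and 8.65% of LMPP 1_1 and 2_1. B lineage genes went the other way, with 6 of 17 lower in the libraries numbered 2 (camera adjusted p = 1.05e-50, and 0.00382 with an estimated correlation). By edgeR quasi-likelihood tests 36 genes rose and 41 fell of 12015 tested (n = 2 versus 2).

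A minority of strongly stimulated cells would leave many cells with no immediate early transcript. At 1000 UMIs per cell the share with none was 23.1 and 21.3% in LMPP 1_2 and 2_2, against 16.2 and 15.9% for an even spread. In LMPP 1_1 and 2_1 it was 56.1 and 49.2%. These values argue against a small minority as the only source. A larger one is not excluded. Many cells of the libraries numbered 1 held such a transcript too, so cells left unstimulated need not lack one. Dilution by B lineage-like cells in the libraries numbered 1 is argued against by an upper limit of 5.44% for such cells there at 1000 UMIs per cell. Unthinned, 11.7 to 30.3% of the cells of single LMPP libraries held 3 or more B lineage transcripts. Mean immediate early transcripts per 1000 were 0.661 and 0.843 in LMPP 1_1 and 2_1, against 1.82 and 1.84 in LMPP 1_2 and 2_2. Dilution by up to 30.3% of the cells would lower the mean by less than this. The values thus argue against dilution as the whole cause at either depth. Different handling of the libraries numbered 2 stays open. The 66 called genes outside the list do not decide it, as the list need not hold every gene that handling moves. Among them some rose, such as Ccl3 (log2 2.065), and some fell, such as Myc (log2 -1.24). The bound set against handling, no rise in the list, was excluded beforehand by the pattern itself. No biological explanation was tested, as the labels state no difference between the libraries.

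More genes differed between CLP and LMPP than between Flt3pos_mixed and LMPP_gate7. Among 8008 genes tested in both at full depth, 1296 rose and 1050 fell in CLP versus LMPP, against 182 and 160 in the second set. With 2 libraries a group and equal cells and transcripts per library, CLP versus LMPP gave 198 to 250 calls against 66. This ratio of 3 to 3.79, over all pairs of LMPP libraries, argues against unequal depth as the whole cause of the excess. How much of the excess unequal depth made stays open. A batch difference of the CLP libraries as the whole cause of the direction is argued against by the genes called in both sets, which share no library: 93.1% changed the same way, 17 opposite. The same sign in the other set was found for 86% of the genes called in the second set and 72.6% of those called in the first. Whether batch or the different gates made the rest of the excess cannot be told, with 335 called genes whose changes differ between the sets.

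Erythroid transcripts in NP1 were not spread evenly. At 1000 UMIs per cell, 61.3% of NP1 cells held none, against 16.7% for an even spread of free RNA. This argues against evenly spread free RNA as the only source. The cells with 3 or more held 82.4% of these transcripts, against 53.4% for an even spread, in line with a minority of erythroid-like cells in the wells (18 of 124) as the main carriers, though the list stayed higher than in CLP with these cells removed (camera adjusted p = 7.84e-05, but 0.0949 with an estimated correlation). Unthinned, 79 of 124 NP1 cells (63.7%) held 3 or more erythroid transcripts, so a low level in many other wells is not ruled out. This unthinned share is not particular to NP1: it was 74.4% in LSK, 74.7% in LMPP and 60.9% in LMPP_gate7, against 10.5% in CLP. At 1000 UMIs per cell Flt3 transcripts were found in 0 of the 18 erythroid-like cells and in 30.3% of the cells with no erythroid transcript. This does not show that Flt3 was absent. A stricter Flt3 gate in a new sort, which should remove such cells, would tell.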
